A study of Mus musculus with 30 samples.

How the data were processed

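RNA of 30 mouse mammary samples was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 sample per array, per the labels. The values used were the deposited log2 values, 1 per probe set and sample, which were made by robust multi-array averaging (RMA) and Partek, per the submitters' processing notes. Versions, the probe set annotation and the genome build were not given in the sources used here. The values ran from 2.64 to 14.68, and the array medians from 7.64 to 7.75. Lower quartiles ran from 6.32 to 6.57 and upper quartiles from 9.14 to 9.41, with the narrowest spreads in Neu tumors 4 and 6. No further normalization was applied outside the other settings. RMA values carry no measure of background, and the spread between replicates and the number of arrays set the precision. Replicates of a group correlated at 0.924 to 0.99 over genes, and no pair of arrays was identical.

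Samples were grouped by the labels into wild-type gland (n = 3), MMTV-Neu tumor (n = 6), well differentiated WAP-Cre:Pten tumor (n = 13) and poorly differentiated WAP-Cre:Pten tumor (n = 8). All 30 samples were used. The labels call the tumors independent primary tumors. Replicate numbers are names given here in the order of the series, and they pair no samples. The letter case of the titles differs between samples, and this spelling was treated as a mark of an unlabelled batch. For Pten tumors A is Wap-Cre and B is WAP-Cre, all with tumor in lower case, and for Neu tumors A is Tumor and B is tumor, all with MMTV-Neu. The marks of the Neu tumors were added after the data were seen, and their match with those of the Pten tumors is assumed.

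The array holds 35556 probe sets. The annotation listed 23410, of which 21789 had 1 gene symbol and 1621 had several, and 12146 were not listed. Probe sets with 1 symbol were kept, and for the 999 genes with more than 1 such probe set the one with the highest mean over all samples was taken, which gave 19938 genes. Of the probe sets with 1 symbol, 21698 matched the reference table by gene identifier, and 0 symbols changed. In the named genes, other probe sets of the same gene were compared with the chosen one in 24 pairs of probe set and comparison, and 0 had the opposite sign. The pairs include a Pgk1 probe set whose differences equalled those of the chosen one, so these could not disagree. Sizes varied both ways. Mras differed by 0.39 instead of 0.73 for Pten against Neu, and Acaca by -2.93 instead of -2.66 for Pten against gland. Probe sets with several symbols were left out, since their signal cannot be assigned to 1 gene. No probe set listed Pten, Carmn, Kras or Hras alone, and these genes were not analysed here.

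Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with the 4 groups in 1 fit that shared the estimate of the spread. The contrasts were poorly minus well differentiated Pten tumors, the mean of both Pten groups with equal weights minus Neu tumors, the same mean minus gland, and Neu tumors minus gland. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 19938 genes, and differences of at least 2-fold were counted apart. Errors are standard errors of the log2 difference. Beside an adjusted p, the number of samples in the first group that lay beyond the mean of the second group, in the direction of the difference, is given.

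Lists of genes for cell types, epithelial lineages and pathways were fixed in advance, 23 lists with 345 genes, of which 321 had a probe set of their own and 5 stood on more than 1 list. They were luminal epithelium, milk secretion, basal and myoepithelium, squamous, mesenchymal, fibroblast, adipocyte, endothelium, smooth muscle and pericyte, skeletal muscle, T and NK cell, B and plasma cell, macrophage, neutrophil, proliferation, Ras and MAPK output, Ras pathway components, reported miR-143 and miR-145 targets, FoxO targets, Wnt targets, interferon response, hypoxia and glycolysis, and lipid synthesis. The reported targets were collected from general knowledge and not from these samples. Each list was tested in each comparison with camera at a preset correlation between genes of 0.01, with p values adjusted over the 92 tests. Camera with an estimated correlation and fry were the alternatives. Of the 92 tests 51 passed with the preset correlation, 0 with an estimated correlation (limma camera) and 46 with fry. List members were also counted with p values adjusted over the list alone. A list score is the mean log2 value of the measured members in a sample.

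Genes were named by a rule. For each comparison it took the 8 called genes with the largest rise and the 8 with the largest fall, leaving out predicted and unnamed genes, the 8 key genes Pten, Erbb2, Mir143, Mir145a, Carmn, Kras, Hras and Nras, of which 4 had a probe set of their own, and for each list up to 4 members with the largest difference among those called, or among all members where the list had no call. The text names part of these genes. Groups, contrasts, lists, this rule and the first set of settings below were chosen before the data were examined.

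The other settings tried were quantile normalization again, arrays centred on their medians, leaving out the 30% dimmest genes (5981), other choices of probe set, an intensity trend with a robust prior, array quality weights, only the groups compared in the fit, the title spelling as a block or within each spelling, each gland left out in turn, the Pten histologies pooled or apart, and scores of B cell, adipocyte and skeletal muscle lists as covariates. Settings chosen after seeing the data were leaving out poorly differentiated tumor 5, well differentiated tumor 13 or both, leaving out the 6 tumors with skeletal muscle scores above every gland, title spelling in the comparisons with Neu tumors or glands, and spelling B without tumor 5. A gene or list is called reversed when it changed sign and was called in either setting. Counts were set against up to 100 splits of the same samples.

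The procedure was tested on simulated data with the group sizes and the gene spreads of the study and independent normal errors, with 50 changed genes per fold size. At simulated log2 changes of 0.5, 1, 2 and 3 it recovered 70%, 92%, 98% and 100% between the histologies, 60%, 84%, 98% and 100% for Pten against Neu, 30%, 86%, 98% and 98% for Pten against gland and 28%, 84%, 92% and 96% for Neu against gland. Unchanged genes made up 4.76%, 3.39%, 3.7% and 5.06% of the calls.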

Results

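Expression was measured in 30 mouse mammary samples, each on 1 Affymetrix Mouse Gene ST array, whose probes cover whole transcripts. The samples were 3 wild-type mammary glands, 6 tumors of MMTV-Neu mice, in which a viral mammary promoter drives the Neu (Erbb2) oncogene, and 21 tumors of WAP-Cre:Pten mice, in which Cre recombinase made in mammary epithelium deletes the tumor suppressor Pten. By histology the labels divided the Pten tumors into 13 well differentiated and 8 poorly differentiated tumors. The tumor codes in the titles start with J in poorly differentiated tumors 1, 2 and 8 and with P in all other Pten tumors. The meaning of this letter is not known here, and its effect was not tested. No well differentiated tumor has a J code, so the letter overlaps with histology, and no setting left these tumors out. The codes in the gland titles start with FvB, which may name a mouse strain, and the tumor titles carry no such code. A strain difference between the groups could not be told apart from the group differences. The labels describe the tumors as independent primary tumors, and each tumor or gland counted as 1 replicate. Array medians lay between 7.64 and 7.75 on the log2 scale, and the first 3 principal components held 25.9%, 17.5% and 11% of the variance. The titles of the Pten tumors wrote the model as Wap-Cre (called A here, 5 well and 4 poorly differentiated tumors) or WAP-Cre (B, 8 and 4). Those of the Neu tumors wrote Tumor (A, 3) or tumor (B, 3), and that A and B match across the models is assumed. The Neu tumors of the 2 spellings differed in 1872 genes (limma, 5534 at an unadjusted p under 0.05), whereas the Pten tumors differed in 0 genes (limma, 2889 unadjusted), so values within each spelling are given where they change a result. Across genes, which are not independent replicates, the spelling differences of the 2 models correlated at 0.458, and whether a batch lay behind this was not tested. On the third component well differentiated tumors lay at 1.06 to 14.89 (A) and -22.83 to -7.85 (B, except tumor 13 at 27.26). Neu tumors lay at -6.37 to 4.46 (A) and -32.80 to -24.40 (B). Poorly differentiated tumors of the 2 spellings overlapped, at 6.69 to 55.62 (A) and -20.01 to 32.30 (B). The lack of calls thus does not show that spelling left no mark in Pten tumors. The number of arrays limits the precision of every value. Signal above background was not measured, so no size is given where a group mean of a gene lay below the lower quartile of every array (6.32 at the lowest), and sizes near that level are uncertain.

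Erbb2 checked the Neu labels. Its level was 11.89 ± 0.23 in the Neu tumors (mean ± SD, n = 6), against 8.98 ± 0.20 in the glands (n = 3), 9.71 ± 0.29 in the well differentiated Pten tumors (n = 13) and 9.76 ± 0.46 in the poorly differentiated ones (n = 8). The Pten deletion was not checked, because no probe set listed Pten alone, so Pten was not analysed here. Kras, Hras and Carmn, the host gene of the miR-143 and miR-145 hairpins, were likewise not analysed here. The series title names these 2 microRNAs, Ras signaling and basal-like tumors that lack Pten, and Mir143, Mir145a and Nras were therefore reported in every comparison.

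The first comparison asked how the 2 histologies of Pten tumors differed. Basal and myoepithelial genes were lower in the poorly differentiated tumors (n = 8) than in the well differentiated tumors (n = 13). Krt5, the keratin of basal epithelial cells, fell by 3.48 ± 0.47 on the log2 scale (± SE, adjusted p = 8.58e-05, below the well differentiated mean in 7 of 8 tumors). Cnn1, Myl9, Myh11 and Tagln, whose proteins belong to the contractile apparatus of smooth muscle and myoepithelial cells, differed by -3.73 ± 0.62, -3.05 ± 0.43, -2.93 ± 0.48 and -2.30 ± 0.38, each lower in 7 of 8 tumors. Mir145a, the gene of miR-145, fell by 2.55 ± 0.39 (adjusted p = 0.000257, 7 of 8 tumors), and Mir143 fell by 0.64 ± 0.16 (adjusted p = 0.0107, 7 of 8 tumors). Their probe sets do not measure the mature microRNAs. In well differentiated tumors Mir145a was at the level of the gland, 10.28 ± 0.78 against 10.29 ± 0.23, and in poorly differentiated tumors it was at 7.73 ± 1.37. Other large falls were those of Defb1, a beta-defensin (-3.43 ± 0.65), Fgb, a fibrinogen chain (-3.30 ± 0.68), Maob, monoamine oxidase B (-2.92 ± 0.50), and Fmod, a collagen-binding proteoglycan (-2.89 ± 0.49). Among the largest rises were those of Fetub, a secreted protease inhibitor (2.38 ± 0.60), Chn2, a Rac GTPase-activating protein (2.17 ± 0.47), Gpx2, a glutathione peroxidase (2.00 ± 0.59), and Slc6a14, an amino acid transporter (1.90 ± 0.41). Erbb2 and Nras differed by 0.05 ± 0.14 and 0.06 ± 0.08, which did not pass the threshold (adjusted p = 0.846 and 0.643, higher in 5 of 8 and 7 of 8 tumors).

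**Figure D1:**
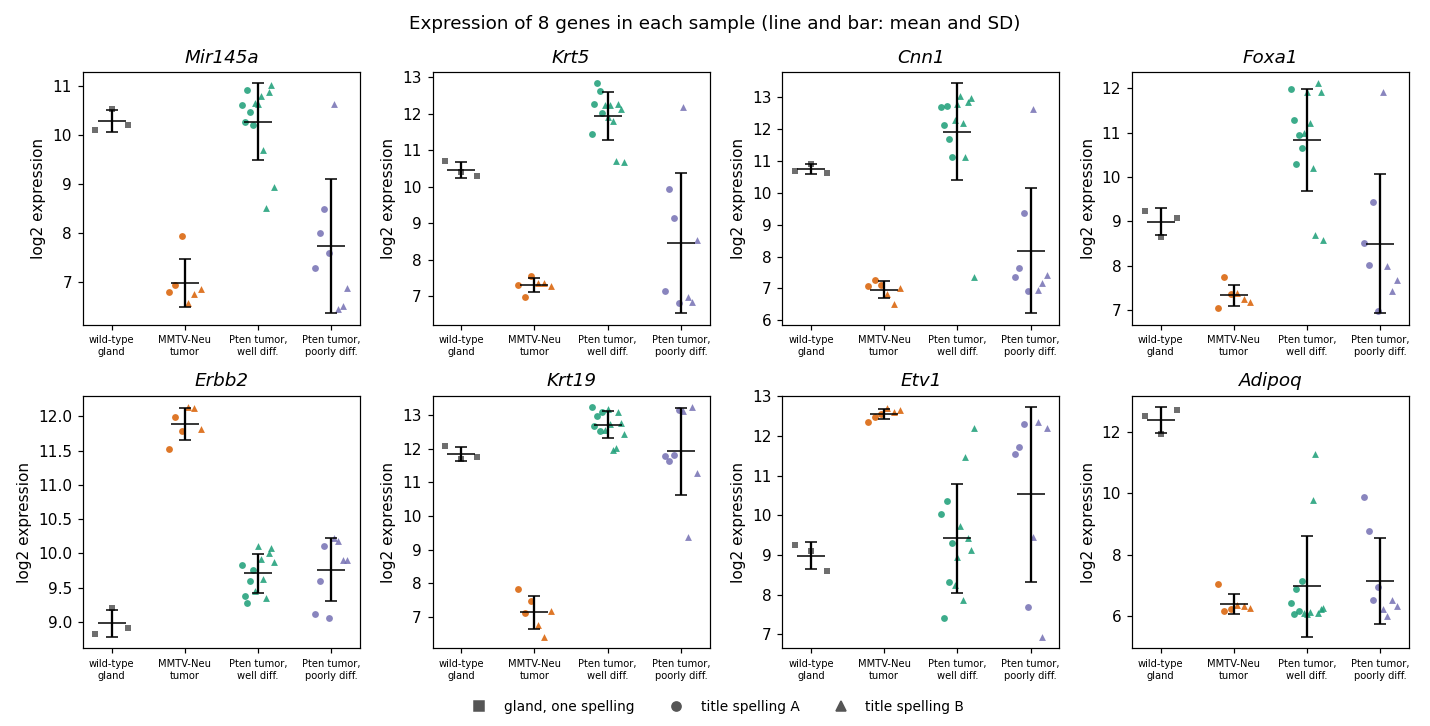
Log2 expression of Mir145a, Krt5, Cnn1, Foxa1, Erbb2, Krt19, Etv1 and Adipoq (vertical axes) in each sample of the 4 groups (horizontal axes). Points are samples, with squares for glands and circles and triangles for tumors of title spellings A and B, and the lines and bars give the mean and SD. Mean Mir145a was 10.29 in glands, 6.98 in Neu tumors, 10.28 in well and 7.73 in poorly differentiated Pten tumors, where 1 tumor, number 5, stood at 10.64.

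By gene list, 11 of the 14 measured basal and myoepithelial markers fell and 3 were not called (1 rose and 13 fell alone when p values were adjusted over the list alone, given below as counts alone). The basal list fell as a set, with a median of -1.48 (adjusted p = 2.35e-16, but adjusted p = 0.0532 with an estimated correlation). The smooth muscle and pericyte list fell as a set, with 5 of 10 genes down (6 fell alone), among them Kcnmb1 (-2.48 ± 0.44) and Actg2 (-2.17 ± 0.38). The smooth muscle list had a median of -0.50 (adjusted p = 9.58e-05, but adjusted p = 0.139 with an estimated correlation). Of 18 luminal genes 4 fell (1 rose and 4 fell alone), namely the hormone receptors Pgr (-2.00 ± 0.38) and Esr1 (-1.37 ± 0.27) and the luminal transcription factors Foxa1 (-2.34 ± 0.48) and Gata3 (-0.76 ± 0.22). The luminal list had a median of -0.14 (adjusted p = 0.0101, but adjusted p = 0.301 with an estimated correlation). The milk protein and secretion genes Btn1a1 (-2.76 ± 0.44), Csn2 (-2.53 ± 0.57) and Csn1s1 (-2.31 ± 0.47) were the 3 of 14 that fell (6 fell alone). The milk list had a median of -1.65 (adjusted p = 2.5e-06, but adjusted p = 0.205 with an estimated correlation). On the mesenchymal list 5 of 19 fell (7 fell alone), including Snai2, a transcription factor that basal mammary cells also express (-2.19 ± 0.29), the cadherin Cdh2 (-1.78 ± 0.34) and the matrix protease Mmp2 (-1.75 ± 0.26). The mesenchymal list had a median of -0.34 (adjusted p = 1.56e-05, but adjusted p = 0.274 with an estimated correlation).

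Markers of other cell types moved with histology too. Endothelial (3 of 12 genes fell, 6 fell alone), macrophage (3 of 12, 6 fell alone), T and NK cell (3 of 11, 3 fell alone) and fibroblast lists (3 of 12, 3 fell alone) fell as sets at the preset correlation. The medians were -0.36, -0.48, -0.26 and -0.29. Their set tests gave adjusted p = 6.9e-05, 0.000253, 0.00232 and 0.00805, and adjusted p = 0.301, 0.352, 0.325 and 0.49 with an estimated correlation. The call of the fibroblast list ended with the content scores as covariates (median -0.08, adjusted p = 0.101). The adipocyte list (1 down of 13, 1 fell alone) had a median of -0.15 (adjusted p = 0.0434, but adjusted p = 0.64 with an estimated correlation). Without the 6 tumors with high skeletal muscle scores, described below, it was at 0.19 (adjusted p = 0.933). The proliferation list rose as a set, with 6 of 23 genes up (12 rose alone), such as Rrm2, a ribonucleotide reductase subunit (1.01 ± 0.23), and Foxm1, a mitotic transcription factor (0.58 ± 0.13). It had a median of 0.41 (adjusted p = 7.49e-06, but adjusted p = 0.435 with an estimated correlation). Of 23 genes induced by Ras and MAPK signaling 2 rose (2 rose alone), the growth factor Hbegf (1.09 ± 0.29) and the cytokine Lif (0.58 ± 0.17). The Ras output list had a median of 0.37 (adjusted p = 0.00669, but adjusted p = 0.513 with an estimated correlation). The interferon list rose as a set, with 2 of 12 genes up (7 rose alone), with Rsad2 at 1.30 ± 0.38. It had a median of 0.80 (adjusted p = 0.00245, but adjusted p = 0.49 with an estimated correlation). The hypoxia and glycolysis list rose as a set, with 2 of 13 genes up (5 rose alone), with Ankrd37 at 0.49 ± 0.13 and Pgk1 at 0.39 ± 0.10. The hypoxia list had a median of 0.39 (adjusted p = 0.0158, but adjusted p = 0.408 with an estimated correlation). Among 16 reported targets of miR-143 and miR-145, 0 passed (limma, 3 at an unadjusted p under 0.05), and Klf5 and Hk2 showed the largest differences, 0.47 ± 0.17 and 0.42 ± 0.15 (adjusted p = 0.0649 and 0.0708, higher in 6 of 8 and 7 of 8 tumors). The target list did not pass as a set (16 not called, median 0.08, adjusted p = 0.727). Ras pathway components (1 down of 15, median 0.07, adjusted p = 0.83), FoxO targets (2 down of 15, 1 up and 2 down alone, median -0.06, adjusted p = 0.439) and Wnt targets (1 up and 1 down of 11, 1 up and 2 down alone, median -0.04, adjusted p = 0.43) did not pass either. Squamous (1 up and 2 down of 19, 1 up and 2 down alone, median 0.02, mean -0.11, adjusted p = 0.611), skeletal muscle (12 not called, median -0.26, adjusted p = 0.169) and B and plasma cell lists (1 down of 10, 1 down alone, median -0.02, adjusted p = 0.418) did not pass. Neutrophil (1 up of 10, 1 up alone, median 0.16, adjusted p = 0.339) and lipid synthesis lists (1 up of 10, 3 up alone, median -0.03, mean 0.13, adjusted p = 0.611) were not called as sets. Median and mean of the squamous and lipid lists differed in sign.

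In all, 2173 of 19938 genes differed between the histologies, 1026 higher and 1147 lower in poorly differentiated tumors, and of the 327 that differed at least 2-fold 40 were higher and 287 lower. Poorly differentiated tumor 5 stood apart from its group, and without it 3702 genes differed. Within spelling A 812 genes differed and Mir145a by -2.66, whereas within spelling B 0 genes did (limma, 1987 at an unadjusted p under 0.05), with Mir145a at -2.52 (adjusted p = 0.469). Without tumor 5 the count within spelling B was 206. The calls of the luminal, fibroblast, endothelial, T and NK cell and hypoxia lists ended within spelling B (medians -0.01, -0.03, -0.08, -0.01 and 0.13), and those of the adipocyte and interferon lists within spelling A (0.03 and 0.67), with the differences between spellings not tested. In 6 tumors (3 well differentiated, 2 poorly differentiated and 1 Neu) the skeletal muscle score lay above that of every gland, highest in well differentiated tumors 9 and 10 (11.33 and 10.67). Poorly differentiated tumor 5 and well differentiated tumor 13 were also among them (9.21 and 7.66). Without these 6 tumors 3576 genes differed between the histologies, with Mir145a at -3.53.

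The second comparison set the Pten tumors (n = 21, both histologies weighted equally) against the Neu tumors (n = 6). Krt19, a luminal keratin, was higher in the Pten tumors by 5.18 ± 0.34 (adjusted p = 4.51e-12, above the Neu mean in 21 of 21 tumors). AI506816, whose function is not described in the sources used here, was also higher (21 of 21), with a Neu mean of 5.17. Also higher than in the Neu tumors were Pdlim3, an actin-associated protein (3.94 ± 0.36), Cbr2, a carbonyl reductase (3.52 ± 0.39), Apod, apolipoprotein D (3.26 ± 0.57), and Hp, haptoglobin (3.22 ± 0.56). Erbb2, the oncogene of the Neu model, was lower in the Pten tumors by 2.16 ± 0.15 (adjusted p = 1.62e-11, 21 of 21). Mmp16, a membrane-bound matrix protease (-4.72 ± 0.21), Alkal2, a ligand of the receptor Alk (-4.41 ± 0.26), Duox1, a hydrogen peroxide-making oxidase (-4.25 ± 0.45), Eya1, a developmental coactivator (-3.58 ± 0.33), and Pcdh10, a protocadherin (-3.54 ± 0.18), were lower in 21 of 21 tumors each. Rises and falls in this comparison are relative to the Neu tumors. Apod and Cbr2 were at 11.74 and 12.16 in the glands and 8.39 and 8.91 in the Neu tumors. Alkal2 and Pcdh10 were at 6.95 and 6.43 in the glands and 11.15 and 10.12 in the Neu tumors. AI506816 went the other way, near its Neu mean in the glands (5.81) and at 10.88 in well differentiated Pten tumors. Mmp16 and Duox1 lay between the models in the glands (8.13 and 9.52). Mir145a was higher in the Pten tumors by 2.03 ± 0.40 (adjusted p = 0.000541, 18 of 21), while Mir143 (0.32 ± 0.16, adjusted p = 0.146, 16 of 21) and Nras (0.11 ± 0.09, adjusted p = 0.359, 16 of 21) did not pass.

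Against the Neu tumors, 10 of 14 basal and myoepithelial markers rose and 1 fell (10 rose and 1 fell alone), with Cnn1 at 3.08 ± 0.64, Krt5 at 2.89 ± 0.48 and Krt14, another basal keratin, at 2.76 ± 0.46. The basal list had a median of 1.51 (adjusted p = 1.72e-07, but adjusted p = 0.139 with an estimated correlation). Mesenchymal genes rose, 11 of 19 called (13 rose alone), led by the membrane protease Mmp14 (2.38 ± 0.19) and Mmp2 (1.67 ± 0.27). The mesenchymal list had a median of 0.91 (adjusted p = 4.71e-10, but adjusted p = 0.132 with an estimated correlation). Among 18 luminal genes 5 rose and 4 fell (6 rose and 4 fell alone), with rises of Krt19, Foxa1 (2.33 ± 0.50) and Krt7 (1.67 ± 0.40). The luminal list had a median of 0.16 (adjusted p = 0.0156, but adjusted p = 0.325 with an estimated correlation). The fibroblast list rose as a set, with 5 of 12 genes up (7 rose alone), such as the matrix proteins Dcn (2.85 ± 0.46) and Postn (2.42 ± 0.34). It had a median of 0.74 (adjusted p = 1.84e-05, but adjusted p = 0.274 with an estimated correlation). Smooth muscle and pericyte (5 of 10 genes rose, 6 rose and 1 fell alone), endothelial (3 of 12, 3 rose alone), macrophage (2 of 12, 2 rose alone), adipocyte (2 of 13, 2 rose alone) and neutrophil lists (1 of 10, 1 rose alone) rose as sets at the preset correlation. Their medians were 0.44, 0.34, 0.37, 0.49 and 0.20, with adjusted p = 0.00345, 0.000767, 0.000564, 0.0135 and 0.0296. With an estimated correlation these 5 gave adjusted p = 0.274, 0.372, 0.372, 0.555 and 0.372. Hypoxia and glycolysis genes rose as a set, with 4 of 13 up, including Ndrg1 (1.24 ± 0.22), and 1 down (4 rose and 1 fell alone). The hypoxia list had a median of 0.20 (adjusted p = 0.00791, but adjusted p = 0.359 with an estimated correlation).

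Of the 23 Ras and MAPK output genes 8 were lower and 2 higher in the Pten tumors (2 rose and 9 fell alone). The falls included the Ets factors Etv1 (-2.58 ± 0.65) and Etv5 (-1.91 ± 0.39), the receptor Epha2 (-1.74 ± 0.34) and the MAPK phosphatase Dusp6 (-1.56 ± 0.38). This list did not pass as a set (median -0.25, adjusted p = 0.234). Among 15 Ras pathway components Nf1, a Ras GTPase-activating protein, fell by 0.95 ± 0.16 (adjusted p = 6.59e-05, 21 of 21) and 3 rose, such as Mras (0.73 ± 0.18). This list did not pass (3 up and 1 down of 15, 3 up and 1 down alone, median 0.11, adjusted p = 0.0811). Milk secretion (1 up and 6 down of 14, 1 up and 7 down alone, median -0.81, adjusted p = 0.268) and lipid synthesis lists (3 down of 10, 3 down alone, median -0.15, adjusted p = 0.361) did not pass as sets. FoxO targets (2 up and 5 down of 15, 2 up and 5 down alone, median -0.12, adjusted p = 0.611) and reported miR-143 and miR-145 targets (1 up and 2 down of 16, 1 up and 2 down alone, median 0.11, adjusted p = 0.116) did not pass. Squamous (4 up and 2 down of 19, 5 up and 2 down alone, median 0.09, adjusted p = 0.096), Wnt target (1 down of 11, 1 down alone, median -0.06, adjusted p = 0.791) and interferon lists (1 up and 1 down of 12, 1 up and 1 down alone, median -0.09, adjusted p = 0.823) did not pass either. Cell division genes (23 not called, median 0.02, adjusted p = 0.244) and skeletal muscle genes (12 not called, median 0.23, adjusted p = 0.216) were not called as sets. T and NK cell (1 down of 11, median -0.13, adjusted p = 0.438) and B and plasma cell lists (10 not called, median -0.03, mean 0.08, adjusted p = 0.727) were not called. The Wnt target list had a mean of 0.02 and the interferon list was ranked upward by the set test, both opposite in sign to their medians.

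Of 19938 genes 5155 differed, 1979 higher and 3176 lower in the Pten tumors, and at least 2-fold 461 were higher and 289 lower. Poorly differentiated Pten tumors alone (n = 8) differed from the Neu tumors in 2561 genes, and well differentiated ones alone in 7226, with Mir145a at 3.31. In the poorly differentiated tumors the differences of Mir145a (0.76), Krt5 (1.15), Cnn1 (1.22), Foxa1 (1.16), Mmp2 (0.79), Etv1 (-2.03) and Dusp6 (-1.22) did not pass, nor did the luminal, smooth muscle, endothelial and adipocyte lists. Where spellings were matched across the models, as assumed, 1059 genes differed within A and 5213 within B. Within spelling A the calls of Apod (2.75), Krt7 (1.55), Etv1 (-2.51), Etv5 (-1.87), Epha2 (-1.41), Dusp6 (-1.59), Nf1 (-0.76) and Mras (0.56) ended. Without the 30% dimmest genes the share that was higher was 50.6% instead of 38.4%.

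**Figure D2:**
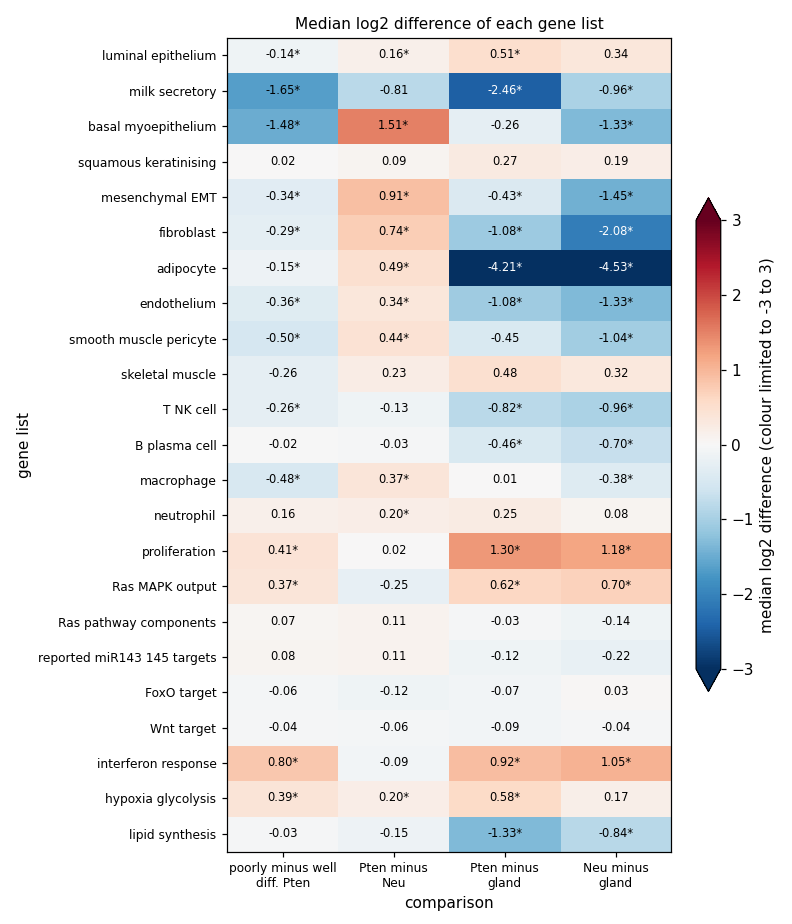
Median log2 difference of the measured members of each of the 23 gene lists (rows) in the 4 comparisons (columns). Colour and number give the median, with colour limited to -3 and 3, and an asterisk marks adjusted p under 0.05 with the preset correlation, none of which held with an estimated correlation. The adipocyte list had medians of -4.21 and -4.53 against the gland, and the basal list -1.48 between histologies and 1.51 between Pten and Neu tumors.

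Against the wild-type gland (n = 3), the Pten tumors (n = 21) had lower fat markers and higher cell cycle genes. All 13 measured adipocyte markers fell, among them the adipokine Adipoq (-5.33 ± 0.79, 21 of 21) and the lipid droplet proteins Plin1 (-4.51 ± 0.42) and Cidec (-4.46 ± 0.68). Of the proliferation genes 22 of 23 rose, such as the cell cycle kinases Cdk1 (1.69 ± 0.19) and Plk1 (1.64 ± 0.25). All 13 and 23 genes of these lists were called when adjusted over the list alone. The fat list had a median of -4.21 (adjusted p = 6.51e-20, but adjusted p = 0.0532 with an estimated correlation). The cell cycle list had a median of 1.30 (adjusted p = 4.49e-17, but adjusted p = 0.142 with an estimated correlation). Among the largest rises were those of Car12, a carbonic anhydrase (3.81 ± 0.32), Gpx2 (3.62 ± 0.81), Tspan8, a tetraspanin (3.25 ± 0.54), and Hey1, a Notch target (2.97 ± 0.43). Ucp1, the uncoupling protein of brown fat (-5.22 ± 0.27, with a gland SD of 1.33), the immunoglobulin gene Igkv10-96 and Gys2, glycogen synthase, fell as well, each in 21 of 21 tumors. Erbb2 was higher than in the gland by 0.76 ± 0.20 (adjusted p = 0.00665, 21 of 21). Mir145a (-1.28 ± 0.54, adjusted p = 0.101, lower in 12 of 21), Mir143 (-0.37 ± 0.22, adjusted p = 0.272, 12 of 21) and Nras (-0.11 ± 0.11, adjusted p = 0.553, 18 of 21) did not pass. In the poorly differentiated tumors alone Mir145a was below the gland by 2.56 (adjusted p = 0.00199), and in the well differentiated tumors alone the difference was -0.01 (adjusted p = 0.996).

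Endothelial, lymphocyte and fibroblast lists were lower in the Pten tumors than in the gland, but none was called with an estimated correlation. Endothelial genes fell in 10 of 12 cases (10 fell alone), including the receptors Tek (-2.16 ± 0.40) and Kdr (-1.48 ± 0.25). T and NK cell genes fell in 8 of 11 (8 fell alone), including Cd3g (-2.31 ± 0.31). B and plasma cell genes fell in 5 of 10 (5 fell alone), including Jchain, the joining chain of antibodies (-4.83 ± 0.90). The endothelial list had a median of -1.08 (adjusted p = 2.49e-08, but adjusted p = 0.142 with an estimated correlation). The T and NK cell list had a median of -0.82 (adjusted p = 5.63e-07, but adjusted p = 0.132 with an estimated correlation). The B and plasma cell list had a median of -0.46 (adjusted p = 0.00128, but adjusted p = 0.132 with an estimated correlation). Fibroblast genes fell in 4 of 12 cases (5 fell alone), with Pdgfra at -2.07 ± 0.33, and mesenchymal genes in 7 of 19 (7 fell alone), with Zeb2 at -2.02 ± 0.34. The fibroblast list had a median of -1.08 (adjusted p = 0.000728, but adjusted p = 0.372 with an estimated correlation). The mesenchymal list had a median of -0.43 (adjusted p = 0.00828, but adjusted p = 0.49 with an estimated correlation). Lipid synthesis enzymes fell, 7 of 10 with 2 higher (2 rose and 7 fell alone), including Acaca (-2.66 ± 0.27) and Fasn (-2.47 ± 0.31). The lipid synthesis list had a median of -1.33 (adjusted p = 4.23e-05, but adjusted p = 0.132 with an estimated correlation). Milk secretion genes fell in 8 of 14 cases (9 fell alone), with Wap, whey acidic protein, at -4.65 ± 1.15 and Glycam1, a mucin-like milk protein, at -5.05 ± 1.41. The milk list score was 12.83 ± 0.46 in the glands (mean ± SD). There Csn2 was at 14.42 and Wap at 14.07, near the highest value of any array (14.68). The adipocyte list score was 12.10 ± 0.30 in the glands, 7.72 ± 0.34 in Neu tumors, and 8.31 ± 1.04 and 8.09 ± 0.81 in well and poorly differentiated Pten tumors. Whether the state or tissue make-up of the 3 glands accounts for the lower milk, fat and lipid synthesis genes was not tested. Nor was it tested for the other differences of either tumor model from the gland, higher or lower. The milk list had a median of -2.46 (adjusted p = 3.33e-05, but adjusted p = 0.274 with an estimated correlation). Luminal genes were higher as a set, with 7 of 18 up, including the keratins Krt8 (0.95 ± 0.15) and Krt18 (0.96 ± 0.15), and 2 down (8 rose and 2 fell alone). The luminal list had a median of 0.51 (adjusted p = 0.0158, but adjusted p = 0.325 with an estimated correlation). Ras and MAPK output genes rose in 7 of 23 cases (8 rose alone), such as Ccnd1, cyclin D1 (1.44 ± 0.21), and Ier3 (1.66 ± 0.40). The Ras output list had a median of 0.62 (adjusted p = 0.00235, but adjusted p = 0.475 with an estimated correlation). As sets the interferon list rose, with 3 of 12 genes up (3 rose alone) and Ifit1 at 2.31 ± 0.55, and the hypoxia and glycolysis list, with 5 up and 1 down of 13 (6 rose and 1 fell alone), with Car9 at 1.99 ± 0.40. The interferon list had a median of 0.92 (adjusted p = 0.00165, but adjusted p = 0.475 with an estimated correlation). The hypoxia list had a median of 0.58 (adjusted p = 0.00413, but adjusted p = 0.325 with an estimated correlation). Basal (14 not called, median -0.26, adjusted p = 0.351), smooth muscle (1 up and 2 down of 10, 1 up and 3 down alone, median -0.45, adjusted p = 0.0654) and squamous lists (2 up of 19, 1 up alone, median 0.27, adjusted p = 0.0652) did not pass. Skeletal muscle (1 down of 12, 1 down alone, median 0.48, adjusted p = 0.628), macrophage (1 up of 12, median 0.01, mean -0.07, adjusted p = 0.823) and neutrophil lists (10 not called, median 0.25, adjusted p = 0.234) did not pass. Ras components (1 down of 15, 1 down alone, median -0.03, adjusted p = 0.727) and miR-143 and miR-145 targets (2 up and 1 down of 16, 2 up and 2 down alone, median -0.12, adjusted p = 0.727) did not pass either. By histology, limma called Krt5 (-2.01, adjusted p = 0.0411), Myh11 (-2.56, adjusted p = 0.0116) and Myl9 (-1.96, adjusted p = 0.0293) lower than the gland in poorly differentiated tumors. In well differentiated tumors these differences were 1.47, 0.38 and 1.08 (adjusted p = 0.14, 0.782 and 0.258). FoxO (2 up and 2 down of 15, 4 up and 4 down alone, median -0.07, adjusted p = 0.823) and Wnt target lists (11 not called, median -0.09, adjusted p = 0.671) were not called. In all 3681 genes differed, 1752 higher and 1929 lower, and 332 and 730 at least 2-fold. Without gland 1, 2 or 3 in turn 2035, 2397 or 2490 genes differed, and the calls of Erbb2 (0.68 without gland 1) and Glycam1 (-4.99 and -5.02 without glands 1 and 2) ended.

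The Neu tumors (n = 6) against the gland (n = 3) also had lower fat markers and higher cell cycle genes, 13 of 13 lower and 22 of 23 higher (13 and 22 adjusted over the list alone). Adipoq differed by -5.99 ± 0.90 and Fabp4, a fatty acid carrier, by -5.06 ± 0.95, and Cdk1 and Tpx2, a spindle protein, by 1.65 ± 0.22 and 1.57 ± 0.31. The adipocyte list had a median of -4.53 (adjusted p = 1.75e-19, but adjusted p = 0.0532 with an estimated correlation). The proliferation list had a median of 1.18 (adjusted p = 3e-10, but adjusted p = 0.274 with an estimated correlation). Erbb2 was higher by 2.92 ± 0.23 (adjusted p = 1.79e-10, 6 of 6 tumors). Krt19 was lower by 4.70 ± 0.51 (adjusted p = 8e-08, 6 of 6), and Mir145a by 3.31 ± 0.61 (adjusted p = 0.000209, 6 of 6). Mir143 was lower by 0.69 ± 0.25 (adjusted p = 0.0423, 6 of 6) and Nras differed by -0.22 ± 0.13 (adjusted p = 0.208, lower in 5 of 6). Among the largest rises were those of Scgb2b27, a secretoglobin (4.87 ± 1.39), Tspan8 (4.70 ± 0.61), the muscarinic receptor Chrm3 (4.66 ± 0.73), Alkal2 (4.20 ± 0.39) and the water channel Aqp5 (4.15 ± 0.48). Among the largest falls was that of Glycam1 (-6.46 ± 1.61), and Igkv10-96 and Jchain were also lower (6 of 6 and 6 of 6).

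Ras and MAPK output genes were higher in the Neu tumors than in the gland in 10 of 23 cases (12 rose alone), led by Etv1 (3.57 ± 0.99), Epha2 (3.03 ± 0.52), Etv5 (2.97 ± 0.59) and Dusp6 (2.60 ± 0.57). The Ras output list had a median of 0.70 (adjusted p = 0.00102, but adjusted p = 0.452 with an estimated correlation). Basal and myoepithelial genes fell in 11 of 14 cases and 1 rose (1 rose and 11 fell alone), with Cnn1 at -3.77 ± 0.97 and Krt5 at -3.16 ± 0.73. The basal list had a median of -1.33 (adjusted p = 1.36e-05, but adjusted p = 0.22 with an estimated correlation). Fibroblast genes fell in 11 of 12 cases (11 fell alone), with Dcn at -4.18 ± 0.70. Endothelial genes fell in 12 of 12 (12 fell alone), with Tek at -2.67 ± 0.46. Mesenchymal genes fell in 11 of 19 (14 fell alone), with Snai2 at -2.96 ± 0.46. The fibroblast list had a median of -2.08 (adjusted p = 3.1e-08, but adjusted p = 0.158 with an estimated correlation). The endothelial list had a median of -1.33 (adjusted p = 3.71e-11, but adjusted p = 0.132 with an estimated correlation). The mesenchymal list had a median of -1.45 (adjusted p = 3.28e-10, but adjusted p = 0.132 with an estimated correlation). Smooth muscle and pericyte (6 of 10 genes fell, 7 fell alone), T and NK cell (6 of 11, 1 rose and 8 fell alone), B and plasma cell (6 of 10, 6 fell alone) and macrophage lists (2 of 12, 2 fell alone) fell as sets at the preset correlation. Their medians were -1.04, -0.96, -0.70 and -0.38, with adjusted p = 0.000648, 0.000128, 0.00322 and 0.0129. With an estimated correlation these 4 gave adjusted p = 0.198, 0.236, 0.132 and 0.513. As sets the lipid synthesis list fell, with 5 down and 2 up of 10 (2 rose and 6 fell alone), with Acaca at -2.76 ± 0.31, and the milk secretion list, with 5 down and 1 up of 14 (1 rose and 5 fell alone), with Wap at -4.72 ± 1.31. The lipid synthesis list had a median of -0.84 (adjusted p = 0.00424, but adjusted p = 0.271 with an estimated correlation). The milk list had a median of -0.96 (adjusted p = 0.00893, but adjusted p = 0.475 with an estimated correlation). The interferon list rose as a set, with 5 of 12 genes up (5 rose alone), with Usp18 at 2.56 ± 0.60. It had a median of 1.05 (adjusted p = 0.0176, but adjusted p = 0.614 with an estimated correlation). The luminal list had a median of 0.34 but a mean of -0.19 and did not pass (adjusted p = 0.759), with 5 of 18 genes up and 3 down (6 rose and 3 fell alone). Skeletal muscle (1 down of 12, 1 down alone, median 0.32, mean -0.05, adjusted p = 0.742) and neutrophil lists (1 down of 10, 1 down alone, median 0.08, mean -0.26, adjusted p = 0.759) did not pass, and their medians and means also differed in sign. Hypoxia (4 up and 1 down of 13, 4 up and 2 down alone, median 0.17, adjusted p = 0.509), squamous (19 not called, median 0.19, adjusted p = 0.698) and Wnt target lists (11 not called, median -0.04, adjusted p = 0.627) did not pass. Ras components (1 up and 2 down of 15, 1 up and 2 down alone, median -0.14, adjusted p = 0.148), miR-143 and miR-145 targets (1 up and 3 down of 16, 1 up and 3 down alone, median -0.22, adjusted p = 0.203) and FoxO targets (3 up and 1 down of 15, 3 up and 1 down alone, median 0.03, adjusted p = 0.823) did not pass either. Within these lists Nf1 rose by 1.53 ± 0.24 and the target Muc1 fell by 2.12 ± 0.68. In all 4962 genes differed, 2750 higher and 2212 lower, and 503 and 1062 at least 2-fold. Without gland 1, 2 or 3 in turn 3180, 3474 or 3296 genes differed. Calls ended for Scgb2b27 (4.61 without gland 3), Mir143 (-0.47 and -0.64 without glands 2 and 3), Muc1 (-1.97 and -2.03 without glands 1 and 2) and the macrophage list (median -0.34 without gland 1). Neu tumors of spelling A alone differed from the gland in 4152 genes and those of spelling B alone in 9280.

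Both tumor models against the gland shared 1021 genes that were higher and 1333 that were lower, and 10 genes were called in opposite directions. Independent lists of these sizes would share 241.6 and 214.0 genes. The 2 comparisons use the same 3 glands, and in 20 simulations of unchanged groups against those glands the mean number of shared limma calls was 0. Unchanged groups give few calls of any kind, so this does not show how far the shared glands raise the overlap. Across genes, which are not independent replicates, the log2 differences correlated at 0.763 against 0.76 in the simulations, so the shared glands alone can give such a correlation. The covariance was 0.289 against a mean of 0.0402 in the simulations, so the simulated sharing of glands did not give shared differences of that size. The 3 glands were too few to split. Without gland 1, 1355 genes were shared instead of 2354.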

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

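Tests of a swapped label and of a single wrong label for tumor 5 were chosen only after the result was seen, and the test of skeletal muscle in that tumor was set before its result was seen. In each group of 4 to 10 samples, here the 6 Neu and the 8 poorly differentiated Pten tumors, a tumor is given below when its gap to the nearest other tumor exceeded the 95% limit of Dixon's ratio. Of 256 such tests of 105 named genes and 23 list scores 34 passed, and chance gives about 1 in 20, or 12.8. The tests are not independent, since genes of a tumor move together. Values are log2 values, each with the nearest other tumor of the group.

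Poorly differentiated Pten tumor 5 was the highest of its group in 16 of these tests: Cnn1 (12.62, nearest 9.37), Myl9 (12.25, nearest 9.62), Myh11 (11.94, nearest 8.58), Tagln (11.36, nearest 8.81), Defb1 (12.21, nearest 7.84), Maob (10.19, nearest 7.60), Fmod (11.31, nearest 8.84), Kcnmb1 (10.69, nearest 7.44), Cdh2 (9.95, nearest 7.90), Mmp2 (11.32, nearest 10.08), Myl1 (8.25, nearest 6.91), Dsc3 (9.28, nearest 6.52), H2-Eb1 (11.68, nearest 10.78), the basal list score (11.03, nearest 9.43), the smooth muscle and pericyte list score (9.39, nearest 8.53) and the skeletal muscle list score (9.21, nearest 7.63).

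That tumor lay with the well differentiated tumors. On the axis from the mean of the well differentiated (0) to that of the poorly differentiated tumors (1), with each tumor left out of the means it was placed by, it lay at -0.13, within the range of the well differentiated tumors (-0.14 to 0.74) and below the other poorly differentiated ones (0.78 to 1.22). Without genes related to the skeletal muscle score it lay at -0.12, which argues against skeletal muscle as the cause. A wrong histology label for that tumor alone may be the cause, and so may a swapped label with a well differentiated tumor, since 1 well differentiated tumor, number 13, lay past the middle of the axis, although at 0.74 it was below the other poorly differentiated tumors. A tumor of mixed histology was not tested and stays open, and the tumor was kept in its group.

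Poorly differentiated Pten tumor 4 stood apart in Krt7 (7.79, lowest, nearest 10.32), Igkv10-96 (8.55, highest, nearest 6.62), Jchain (9.21, highest, nearest 7.04), Glycam1 (11.31, highest, nearest 8.05) and the neutrophil list score (6.65, lowest, nearest 7.16). Poorly differentiated Pten tumor 1 did so in Plin1 (9.16, highest, nearest 7.98), and poorly differentiated Pten tumor 3 in Alkal2 (7.52, highest, nearest 6.90). Neu tumor 1 stood apart in Defb1 (6.97, highest, nearest 6.22), Adipoq (7.04, highest, nearest 6.38), Hp (9.84, highest, nearest 7.44), Alkal2 (8.84, lowest, nearest 11.17), Epha2 (8.70, lowest, nearest 10.79), Nf1 (11.19, lowest, nearest 12.06) and the neutrophil list score (7.38, highest, nearest 6.69). Neu tumor 3 did so in Mir145a (7.94, highest, nearest 6.94) and Eya1 (7.27, lowest, nearest 10.20), and Neu tumor 6 in Myl1 (8.16, highest, nearest 6.23) and the skeletal muscle list score (7.98, highest, nearest 7.12).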

How the results depend on the processing

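Leaving out tumors 5 and 13, leaving out the tumors with skeletal muscle, spelling B without tumor 5, and title spelling in the comparisons with Neu tumors or glands were tests chosen only after the data were seen, and the others were planned. Of the values of named genes under the alternatives, 4966 kept direction and side of the threshold, 477 kept direction but no longer passed, 39 newly passed and 1 reversed. For list tests the numbers were 1409, 39, 23 and 1. The reversals were Myl1 between the histologies without the tumors with skeletal muscle (0.57, -0.43 in all tumors), and the skeletal muscle list between the histologies within spelling A (median 0.22, -0.26 in all tumors), and the cause was not tested.

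Between the histologies, 2173 genes became 1408 without the dimmest genes, where fewer genes were tested and 28.1% instead of 47.2% of calls were higher, 812 within spelling A, 0 within spelling B (limma, 1987 at an unadjusted p under 0.05), and 206 within spelling B without tumor 5. Leaving out single tumors gave 2363 without well differentiated tumor 13 and 3702 without poorly differentiated tumor 5, leaving out both gave 3941, and leaving out the 6 tumors with skeletal muscle, which include both, gave 3576. Pten against Neu tumors moved from 5155 to 2561 with poorly differentiated tumors only and to 1059 within spelling A, and 50.6% instead of 38.4% of calls were higher without the dimmest genes. Pten tumors against the gland moved from 3681 to 6656 with array quality weights, and to 2035 to 2490 with a gland left out (2035 without gland 1, 2397 without gland 2). Neu tumors against the gland moved from 4962 to 9289 with array quality weights, 9280 with spelling B only, and 3180 to 3474 with a gland left out (3180 without gland 1, 3296 without gland 3). The calls shared by both models against the gland moved from 2354 to 4444 with array quality weights, and to 1355 to 1598 with a gland left out (1355 without gland 1). List calls moved from 51 to 0 of 92 with an estimated correlation (limma camera). The causes of these moves were not tested. Centring the arrays raised the median of all genes in Neu tumors against the gland from 0.111 to 0.165 and the share of calls that were higher from 55.4% to 67.9%. Over all settings with calls the share that was higher ran from 26.7% to 55.9% between the histologies and from 39.4% to 53.9% for Pten tumors against the gland. For calls of any size, neither direction can thus be said to hold more. Among calls of at least 2-fold in the main fit more were lower, 287 against 40 between the histologies and 730 against 332 for Pten tumors against the gland. Every other alternative run left the counts of all calls within 1.5 times.

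Within spellings, 777 of the 812 genes called in spelling A (95.7%) had the same sign in spelling B between the histologies, and 0 were called in both. For Pten against Neu tumors 1033 of 1059 (97.5%) had the same sign, of which 641 were called in both. Over all genes the shares with the same sign were 70.8% and 72.5%. An interaction of histology and spelling was called for 0 genes (limma, 1019 unadjusted). Mir145a between the histologies lay between -3.53 and -2.52 over 17 alternatives and passed in 16. Against the gland, Mir145a in Pten tumors passed in 4 of 17, with -2.56 to -0.01. No paired analysis was possible because the replicate numbers are only names. Signal over background was not analysed here, and the number of arrays limits the precision.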

Other observations

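Some members of lists that did not pass as sets differed between the histologies. Sesn1, a stress-induced FoxO target, was lower in poorly differentiated tumors by 0.77 ± 0.14 (limma adjusted p = 0.000828, 8 of 8 tumors), and Txnip, a thioredoxin-binding protein, by 1.06 ± 0.25 (0.0084, 6 of 8). Of the squamous list, the desmosomal cadherin Dsc3 was lower by 2.01 ± 0.52 (0.0145, 7 of 8) and Dsg3, another one, higher by 1.38 ± 0.36 (0.0138, 7 of 8). Dsc3 was at 9.28 in poorly differentiated tumor 5 and at a mean of 6.03 in the others. That mean lay below the lower quartile of every array, so the size for Dsc3 is uncertain. Insig1, a regulator of sterol synthesis, was higher by 0.81 ± 0.18 (0.00492, 7 of 8). Against Neu tumors, the Pten tumors had less Irs2, an insulin receptor substrate (-1.25 ± 0.19, 2.87e-05, 21 of 21), and less Srebf1, a regulator of lipid synthesis (-1.53 ± 0.20, 3.38e-06, 21 of 21). Within spelling A the calls of Txnip and Dsg3 ended, and within spelling B those of all 5 genes named between the histologies, with Sesn1 at -0.70 and Insig1 at 0.66.

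Of the tests in this part, those of title spelling, the contractile score, tissue content, the neighbour count and the Neu spelling were chosen only after the results were seen, and the splits of the 4 comparisons and the relations of Mir145a to Ras output and to the reported targets were set before their results were seen. In fits of only the groups compared, no other split of the same samples reached the counts between groups. At most 100 splits were run, 84 for Neu against gland. A real group difference widens the spread in the other splits and lowers their counts, so these splits limit chance as a source but do not exclude it. Between the histologies the real split called 1810 genes and the highest of the other splits 1, for Pten against Neu 4845 and 2, for Pten against gland 3548 and 51, and for Neu against gland 5292 and 2225, and in each of the 4 comparisons 1 split, the real one, was as large. The split with 2225 calls set the Neu tumors of spelling B apart, so it points to a structure of the samples. For the 2 spellings of the Neu tumors (1872 genes, highest other split 0) the 10 splits are too few for a share under 0.05.

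The lower Mir145a in poorly differentiated Pten tumors was weighed against 3 explanations. A batch marked by the title spelling was argued against as the whole cause, since the smaller of the differences within spellings was -2.52. Spelling called 0 genes in the Pten tumors, so a batch that it does not mark was not tested and stays open. B cell, fat and skeletal muscle content was argued against too, since the difference was -2.73 with these content scores as covariates. Other tissue content is not in these scores. Fewer cells with the contractile program may account for it: with a score of 11 contractile genes, picked after the largest falls were seen, as a covariate the difference was -0.40 ± 0.36, and with the smooth muscle and pericyte list, fixed before, -0.93 ± 0.38. The contractile score itself separates the histologies (10.4 against 8.33), which limits this test. With that score as a covariate Mir143 also lost its call, at 0.07 ± 0.19 (limma adjusted p = 0.951). Within each histology, in relations added after the results were seen, Mir145a correlated with the contractile score at 0.74 in the 13 well differentiated tumors (permutation p = 0.0283, adjusted over 6 relations) and at 0.919 in the 8 poorly differentiated ones (exact permutation p = 0.0283, adjusted). Without the 2 tumors farthest from the others these fell to 0.478 and 0.307, whereas the rank correlations over all tumors were 0.747 (permutation p = 0.0046, unadjusted) and 0.643 (exact permutation p = 0.0962, unadjusted). Lower Mir145a within the tumor cells themselves was not tested and stays open.

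Whether tumors with less Mir145a have more Ras output or more of the reported targets was tested within each histology, and neither was shown. The correlation of Mir145a with the Ras output score was -0.345 in the 13 well differentiated tumors (permutation p = 0.242, and 0.552 without the 2 tumors farthest from the others) and -0.145 in the 8 poorly differentiated ones (exact permutation p = 0.778). With the target score it was -0.268 (permutation p = 0.374) and -0.395 (exact permutation p = 0.347). The tumors are too few to exclude such a relation.

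Some genes separate all 21 Pten tumors from all 9 other samples, and a different strain background around linked genes may be a source. Only the gland titles carry a code that may name a strain (FvB), and the strains of the tumors are not known here. A neighbour pair was 2 such genes next to each other and at most 20 genes apart on a chromosome. Linkage over a longer distance was not counted, so a lack of pairs does not show that genes are unlinked. The first definition, a gap of at least 1 log2 unit, found 3 genes (AI506816, D17H6S56E-5 and H2-Eb1, the last chosen after its values were seen), with 0 neighbour pairs and a permutation p of 1, and 3 genes are too few for the test. The definition was then changed, after that result, to any complete separation, which found 41 genes (27 higher and 14 lower) with 3 neighbour pairs against a median of 1 in random sets (permutation p = 0.212). That does not decide for or against linked genes, no further definition was tried, and a biological difference between the models stays open.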
